A study of Mus musculus with 22 samples.

How the data were processed

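Hippocampal RNA of adult males was hybridised to 22 Agilent 1-colour arrays of a mouse whole-genome design, with probe positions on mm9 per the file headers. Arrays were grouped by the genotype and collection time in their titles, into 8 groups of 2 or 3, and numbered by the replicate number in the same titles. The titles also carry a number after the letter l, whose meaning the labels do not give; it goes together with the replicate number on every array. Slide number and replicate number match too, except for WT 12 h replicate 2, which was on slide 1.

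The authors deposited, for each array, scanner output whose values are spot intensity on a linear scale. It was made with Agilent Feature Extraction 10.7.3.1, per the file headers, with spatial and multiplicative detrending of the processed signal and no subtraction of local background. The authors also deposited a table of log2 values for all arrays. Its making is not given in the sources used here. Set against the scanner values, every column had the same median of 5.35, each column correlated best with its own array (22 of 22, lowest r 0.999), and all columns held one distribution, as quantile normalization leaves it. Its scale is therefore log2, genes were not centred, and the direction is that of signal. Unused per-sample columns numbered 0.

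From the scanner files, control spots (3671 per array) and spots marked as non-uniform or population outliers were left out. The processed signal of the other spots was averaged per probe and log2 taken, and the array's 75th percentile was subtracted. In all, 162 probes had no usable spot on some array and were left out everywhere. Probes were kept where they were well above background on every array of at least 1 of the 8 groups (34936 probes). Each gene name was then represented by the kept probe with the highest mean level, which gave 24772 features. Probe names came from a RefSeq gene table of assembly GRCm38.p6, used for names and neighbours only, through their accession for 26685 probes and through their symbol for 2538; 23814 kept the name in the file and 2644 had none. No genome was used, so positions are those of the files, on mm9, and exon or UTR annotation is not given. Group values are means and SDs of log2 levels relative to the 75th percentile.

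Tests used limma 3.58.1 in R 4.3.3, with lmFit on the 8 group means over all 22 arrays and eBayes. Contrasts were the mean of the 4 KO groups minus the mean of the 4 WT groups, KO minus WT at each time, an F test between the 4 times over both genotypes and within each, and an F test of the interaction. Benjamini-Hochberg adjusted p under 0.05 was called, two-sided. For collection time the log2 difference is that between the highest and the lowest of the 4 time means, each averaged over the genotypes. A bound of the form "at least N-fold" was given where a probe was well above background in 1 group of a comparison and on no array of the other.

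The 39 gene lists were tested with camera at a preset inter-gene correlation of 0.01, for KO minus WT, 0 h minus 12 h and 6 h minus 18 h, and again with an estimated correlation. Their members were also tested singly, adjusted over all features and adjusted over the list alone. The lists cover the core clock, clock outputs, glucocorticoid response, immediate early genes, heat shock proteins, cold-inducible RNA-binding genes, the unfolded protein response, Rho GTPases and effectors, Rho GAPs and GEFs, cAMP and PKA signalling, clathrin endocytosis, synaptic vesicle release, glutamate receptors, postsynaptic scaffold, GABA receptors and transport, interneurons, neuropeptides and their receptors, dentate granule, CA1 and CA3 with CA2 neurons, adult neurogenesis, astrocytes, oligodendrocytes and myelin, oligodendrocyte precursors, microglia, immune activation, endothelium, pericytes and fibroblasts, choroid plexus, ependyma and cilia, erythrocytes, thalamus and habenula, neocortex, striatum and septum, neighbours of Ophn1 on the X chromosome, oxidative phosphorylation, cytosolic ribosomal proteins, cholesterol synthesis and potassium channels. For 18 lists, chiefly of cell types, the mean level per array was compared between genotypes by an exact two-sided permutation of genotype within collection times, over all 40000 arrangements.

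The design, the lists, the rule for named genes and the alternatives were fixed before the data were examined, except where a text says otherwise. Named genes needed a symbol, and predicted genes, RIKEN clones and unnamed features were left out. Ophn1 was always named. For KO against WT over the 4 times, up to 12 higher and 12 lower genes were named by the largest absolute log2 difference among those that passed with one sign at all 4 times; where fewer than 6 passed in a direction, those with the smallest p were named and stated as not passing. At single times the 3 with the smallest p among those passing were named, for collection time the 24 with the smallest p, and for the interaction up to 10 that passed, or 3 that did not. Every core clock member was named. Of every other list, up to 4 members that passed over all genes or over the list alone were named by smallest p, and otherwise at most 2. A gene that several parts name counts under each.

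The alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization alone, the authors' deposited table, no filter, a filter for probes well above background on all 22 arrays (22229 features), every probe on its own, the mean of a gene's probes, a trended and robust variance, the replicate number as a block, slide as a block, each array left out in turn, only the arrays of 6 and 18 h or of 1 time, a 24 h cosine and sine in place of 4 free times, and a log2 limit of 0.5. After the data were seen, fits were added with the mean of the choroid plexus list as a covariate, with that covariate and slide together, and without the 11 arrays whose Ttr level was above 4. In the last of these, the KO groups of 0, 6 and 12 h and the WT groups of 0 and 12 h held 1 array each. Its estimate of the spread rests on the remaining groups alone. For each count, genotype labels within times, or time labels within genotypes, were redrawn to give 100 splits with the real one, or all 10 splits where 3 arrays were set against 3. With slide as a block, genotypes were instead exchanged within the 10 pairs of a KO and a WT array of one slide and time, for 100 of the 1024 possible splits.

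The fits were tested on simulated data with 200 of 24772 genes changed, in 10 simulations. Noise was drawn independently for each gene and array, without slide, choroid plexus or other variation shared between genes. The shares below therefore hold for such data, not for arrays with that structure. For KO against WT over the 4 times, 72.8%, 95.5% and 99.2% of genes changed by 0.5, 1 and 2 (log2) were recovered, with 4.93% false among the calls. For KO against WT at 18 h the shares were 38.4%, 77.6% and 96.2%. For collection time, with 6 h changed, they were 58.4%, 86.7% and 97.0%, with 4.45% false. Other tools were Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, and statmod 1.5.0 in R.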

Results

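Gene expression was measured in the hippocampus of adult male mice carrying a mutation of Ophn1 (KO) and of control males (WT). Ophn1 encodes oligophrenin-1, a Rho GTPase-activating protein of neurons whose loss causes X-linked intellectual disability in humans. All mice spent 24 h in the dark before collection, and hippocampi were taken at 4 times labelled 0, 6, 12 and 18 h. The labels do not say which hour of day 0 h was. KO groups held 3 arrays at each time. WT groups held 3 arrays at 6 and 18 h and 2 at 0 and 12 h, the times at which the submitters report that controls were excluded on a principal component analysis. Each of the 22 arrays gave the Cy3 signal of 59305 gene spots, which stand for 55681 probes. Between 58.4% and 67.6% of the probes were well above background on an array, the 75th percentile of the signal lay between 326 and 606, and 0 spots were saturated. Arrays of one group correlated at r = 0.987 to 0.994 across probes, which are not independent replicates, arrays of different groups at up to 0.997, and 0 pairs of arrays held identical values. The labels do not say that each array is a separate animal, so the p-values measure only the spread between these samples. The number of arrays, 2 or 3 in a group, limits the precision of every value.

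The arrays sat on 3 slides of 8, 7 and 7 arrays. On each slide WT arrays were in column 1 and KO arrays in column 2, and each slide row held 1 collection time, so position on the slide cannot be told apart from genotype or time. Slides 2 and 3 lacked a WT array at 12 h and at 0 h, respectively. Because each slide held both genotypes, results are also given with slide as a block and within slides.

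Ophn1 itself was lower on every KO array than on every WT array. The probe used for it (X:95753590-95753649, mm9, NM_052976) had a level of -0.92 ± 0.20 (SD, n = 12) in KO and 1.03 ± 0.12 (SD, n = 10) in WT, in log2 units relative to the array's 75th percentile. The difference was -1.94 (SE 0.0662), or 3.83-fold lower in KO, with limma adjusted p = 4.71e-11. KO arrays ranged from -1.06 to -0.32, the highest being an 18 h array of slide 1, and WT arrays from 0.82 to 1.20. A further Ophn1 probe (X:95752865-95752924) lay at -2.60 ± 0.20 (SD, n = 12) in KO and -1.56 ± 0.13 (SD, n = 10) in WT, a smaller difference of -1.03. Both probes were well above background on every array of both genotypes. The sources used here do not give the part of the gene that was mutated, so whether the probes lie inside it is unknown. The difference was -1.93 with slide as a block and -1.79, -2.10 and -1.92 within slides 1 to 3.

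**Figure D1:**
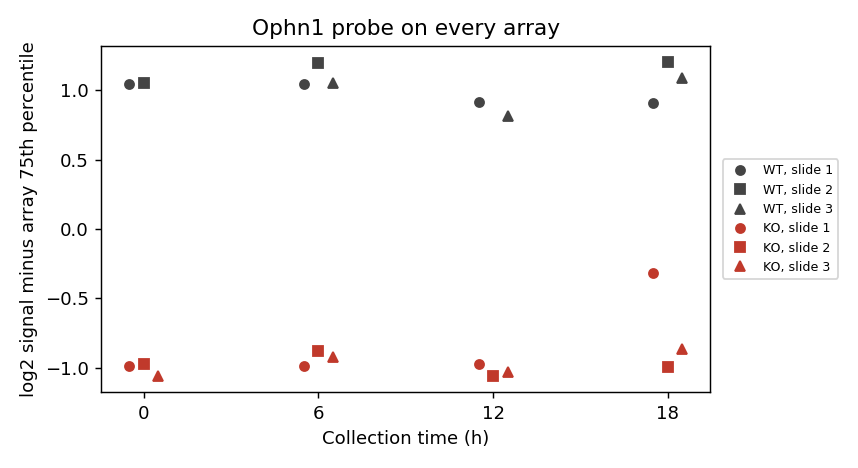
Level of the Ophn1 probe on each of the 22 arrays (vertical axis, log2 signal minus the array's 75th percentile) against collection time in h (horizontal axis). Points are single arrays, grey for WT and red for KO, with a marker shape for each slide. The 12 KO arrays lie between -1.06 and -0.32, and the 10 WT arrays between 0.82 and 1.20.

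The comparison of KO with WT over the 4 times asks which hippocampal genes differ with the Ophn1 mutation whatever the hour. Apart from Ophn1, few genes passed in the fit without slide, whereas 155 features, Ophn1 included, passed with slide as a block. The values that follow are from the fit without slide unless stated. Car9, a membrane carbonic anhydrase induced by low oxygen, was higher in KO by 0.91 (log2, SE 0.134, adjusted p = 0.017), and higher at each of the 4 times (n = 12 KO and 10 WT arrays). Ccn5, a secreted matricellular protein of the CCN family, was also called higher in KO (adjusted p = 0.0101). It was well above background on all 12 KO arrays and on 4 of the 10 WT arrays, none of them of 0 h, so no fold over the 4 times is given. Ugt2b5, a glucuronosyltransferase of steroid and drug metabolism, was called lower in KO (adjusted p = 3.25e-04). Its signal was well above background only on the 2 WT arrays of 12 h, on which the call rests, so no fold over the 4 times is given. Of 24772 features tested, 6 passed, 2 higher and 4 lower in KO. The remaining pair are probes without a gene name, A_55_P2104478 and A_55_P2152184, each at -0.54 (adjusted p = 0.00752 and 0.0107). They were chosen after their values were seen. An unadjusted p under 0.05 was reached by 1775 features, against 1238.6 expected by chance.

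Genes named for the smallest p without passing were, higher in KO, the desmosomal cadherin Dsg1c (not well above background on any WT array of 12 or 18 h, adjusted p = 0.0736), the plasma carboxypeptidase Cpb2 (0.60, SE 0.106, adjusted p = 0.089), Rnase10 of the RNase A family (0.57, adjusted p = 0.119) and the cofilin phosphatase Ssh3 (0.22, adjusted p = 0.12). On the lower side were the lysophosphatidic acid receptor Lpar1 (-0.36, SE 0.0637, adjusted p = 0.089), the glycosyltransferase B3gnt9 (-0.29, adjusted p = 0.129), Relt of the tumour necrosis factor receptor family (-0.21, adjusted p = 0.129) and the potassium channel subunit Kcne1l (-0.23, adjusted p = 0.129). With slide as a block, the 4 higher and the 4 lower genes passed too, with adjusted p between 0.0067 for Lpar1 and 0.0363 for Kcne1l. That fit called 155 features, 66 higher and 89 lower in KO, and it kept all 6 features called without the block. Of the 155, 61 had a symbol in the reference table, 26 higher and 35 lower.

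Within slides 1, 2 and 3, 0, 0 and 2 features passed in limma, and 3860, 2974 and 2973 had an unadjusted p under 0.05. Car9 differed by 0.81, 0.93 and 1.08 within the slides. Ugt2b5 was above background within slides 1 and 3 alone, slide 2 being the one without a WT array at 12 h. The number that passed was 46 without WT 12 h replicate 2, 19 without KO 12 h replicate 3, 15 without WT 0 h replicate 1, 13 without WT 12 h replicate 3 and 11 without KO 0 h replicate 3 or WT 18 h replicate 1. The call of Car9 was lost without KO 0 h replicate 2 or KO 18 h replicate 1 (adjusted p = 0.0513 each), KO 18 h replicate 3 (0.052) or WT 0 h replicate 2 (0.0763). Normexp background correction ended the calls of Ccn5 (adjusted p = 0.0744) and Ugt2b5 (adjusted p = 0.477), and a trended, robust variance that of Ugt2b5 (adjusted p = 0.288). Ccn5, Car9 and Ugt2b5 all lost their calls with only the 6 and 18 h arrays (adjusted p = 0.306, 0.414 and 1) and without the 11 arrays high in the choroid plexus gene Ttr (0.119, 0.160 and 0.0793).

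A measure that RNA quality or labelling can move also differed between the genotypes. In 2076 genes with a pair of probes, the upstream probe relative to the downstream one lay lower in KO by a median of -0.0279 (exact permutation p = 0.00215), and by -0.0138, -0.0316 and -0.0432 within slides 1 to 3. It moved with genotype, as did the list changes that follow, and no list was tested against it. Immediate early genes, which neurons transcribe within minutes of activity, lay higher in KO. Of the 24 measured, 19 were higher, with a list mean of 0.25. Npas4 differed by 0.69, Egr2 by 1.04, Arc by 0.48, Egr4 by 0.36 and Dusp6 by 0.26. No member passed over all genes in limma, 11 had an unadjusted p under 0.05 and 10 passed adjusted over the list alone. The list passed in camera (adjusted p = 7.05e-08), not with an estimated correlation (adjusted p = 0.619 with an estimated correlation). Its mean on each array gave a stratified exact permutation p of 0.0138 (adjusted p = 0.123 over 18 lists). Within slides 1 to 3 the mean difference was 0.31, 0.04 and 0.27, and 0.24 with slide as a block. Choroid plexus genes were also higher in KO, by a list mean of 0.996, and with that signal as a covariate the immediate early list had adjusted p = 5.25e-11 in camera.

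Myelin genes lay lower in KO. All 19 measured members were lower, with a mean of -0.21, among them Mbp, a main protein of the myelin sheath (-0.37, SE 0.0883), the myelin protein gene Opalin (-0.32) and Ugt8a, an enzyme of myelin lipid synthesis (-0.29). In limma no member passed over all genes, 10 had an unadjusted p under 0.05 and 1, Mbp, passed adjusted over the list alone. The list passed in camera (adjusted p = 3.7e-13, adjusted p = 0.619 with an estimated correlation), and its array means gave an exact permutation p of 0.0204 (adjusted p = 0.123). The mean difference was -0.42, 0.00 and -0.21 within slides 1 to 3 and -0.22 with slide as a block. Oligodendrocyte precursor genes had a mean of -0.07, with 6 of 8 members lower (adjusted p = 0.00662; 0.619 as adjusted p with an estimated correlation) and 1, C1ql1 at -0.13, passing adjusted over the list alone; the adjusted p was 0.157 without WT 12 h replicate 2 and 0.335 without the 11 arrays high in Ttr. Microglial genes had a mean of -0.06, with 15 of 17 members lower (adjusted p = 6.57e-04; 0.619 as adjusted p with an estimated correlation; exact permutation p = 0.016, adjusted p = 0.123) and 1, Fcrls at -0.21, passing adjusted over the list alone.

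Genes of ependyma and motile cilia were higher in KO in 13 of 13 members, with a mean of 0.46 (camera adjusted p = 6.76e-10, adjusted p = 0.619 with an estimated correlation; exact permutation p = 0.0297, adjusted p = 0.133). Tmem212 differed by 0.58, Ccdc153 by 0.49 and Meig1 by 0.30; in limma no member passed over all genes, 7 had an unadjusted p under 0.05 and 6 passed adjusted over the list alone. The mean difference was 0.18, 0.99 and 0.46 within slides 1 to 3. The list also passed with the choroid plexus signal as a covariate (camera adjusted p = 3.17e-10). Its mean was 0.53 without the 11 arrays high in Ttr. The choroid plexus is the epithelium beside the ependyma in the ventricles. Its 17 listed genes were all higher in KO, by 0.996 on average and by -0.42, 3.53 and 0.92 within slides 1 to 3 (camera adjusted p = 0.0206, adjusted p = 0.945 with an estimated correlation), but the exact permutation p was 0.360 and 0 members passed or had an unadjusted p under 0.05 in limma. The call held in 9 of the 22 fits that left out 1 array. It was lost without KO 0 h replicates 1 or 2, KO 6 h replicates 2 or 3, KO 12 h replicates 1 or 2, KO 18 h replicate 1, WT 0 h replicate 2, WT 6 h replicates 1 or 2, WT 12 h replicate 3 or WT 18 h replicates 2 or 3 (adjusted p = 0.0808 to 0.837). Without the 11 arrays high in Ttr the list lay higher in KO by 0.64, in a fit where most groups held 1 array.

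The choroid plexus signal split the arrays rather than the groups. Ttr, the transthyretin gene and the most abundant choroid plexus transcript, lay between 6.18 and 8.20 on 11 arrays and between -2.03 and 1.997 on the other 11 (log2 relative to the 75th percentile). The 11 high arrays were 7 of the 12 KO and 4 of the 10 WT arrays. Ttr differed by 2.14 between KO and WT (SE 1.8, adjusted p = 0.889). With the choroid plexus signal as a covariate, 6 features passed between KO and WT, and with only the 11 arrays low in Ttr, 10 passed, 1 of them shared with the 6 above.

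**Figure D2:**
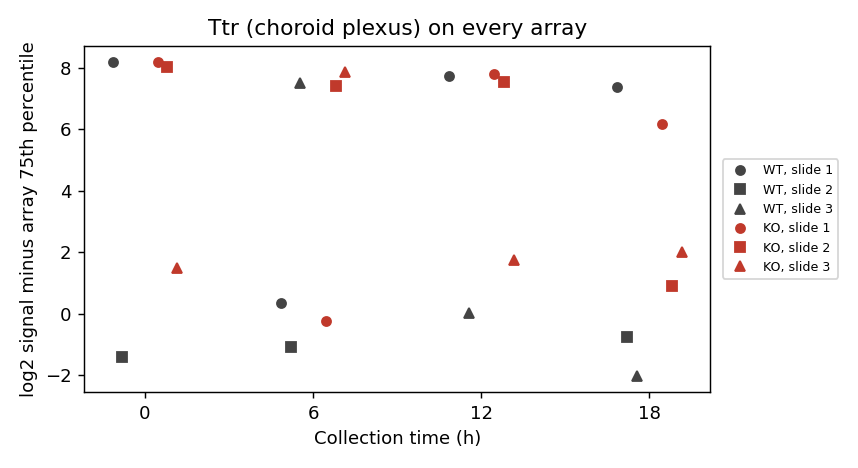
Level of Ttr on each of the 22 arrays (vertical axis, log2 signal minus the array's 75th percentile) against collection time in h (horizontal axis). Points are single arrays, grey for WT and red for KO, with a marker shape for each slide. Arrays of both genotypes and of all 3 slides are found in the upper band, between 6.18 and 8.20, and in the lower one, between -2.03 and 1.997.

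Small shifts of large lists also passed in camera. Cytosolic ribosomal protein genes had a mean of -0.05, with 41 of 43 lower in KO (adjusted p = 3.14e-05, adjusted p = 0.945 with an estimated correlation; 0.941 without WT 12 h replicate 3), Rplp0 at -0.15 being an example. The mean was -0.16 without the 11 arrays high in Ttr and -0.029 with the choroid plexus covariate. Oxidative phosphorylation genes had a mean of -0.04, with 44 of 50 lower (adjusted p = 1.62e-04, adjusted p = 0.945 with an estimated correlation; 0.810 without WT 12 h replicate 3), for example the complex I subunit Ndufs2 at -0.13. Their mean was -0.13 without the arrays high in Ttr and -0.022 with the covariate. Rho GAPs and GEFs, the class that Ophn1 belongs to, had a mean of 0.05, with 26 of 32 higher (adjusted p = 0.00477, adjusted p = 0.830 with an estimated correlation; 0.0577 without WT 0 h replicate 1), for example Arhgap26, of the same protein family as Ophn1, at 0.17. Postsynaptic scaffold genes had a mean of 0.05, with 20 of 22 higher (adjusted p = 0.0298, adjusted p = 0.945 with an estimated correlation; 0.109 with slide as a block and 0.320 without the 11 arrays high in Ttr), for example Dlg2 at 0.15. The scaffold mean was 0.073 with the choroid plexus covariate. The scaffold call held in 12 of the 22 fits that left out 1 array and was lost without KO 0 h replicate 3, KO 6 h replicate 1, KO 12 h replicates 2 or 3, KO 18 h replicates 1 or 2, WT 0 h replicate 1, WT 6 h replicate 3, WT 12 h replicate 2 or WT 18 h replicate 1 (adjusted p = 0.052 to 0.662). Within slides 1 to 3 the means were 0.04, -0.09 and -0.16 for ribosomal proteins, 0.05, -0.06 and -0.14 for oxidative phosphorylation, 0.07, 0.04 and 0.02 for Rho GAPs and GEFs and 0.12, 0.01 and -0.06 for the scaffold.

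The other 29 lists did not pass between KO and WT. They include Rho GTPases and effectors (mean -0.01, adjusted p = 0.924), cAMP and PKA signalling (-0.01, 0.708), clathrin endocytosis (0.01, 0.790), synaptic vesicle release (-0.03, 0.708), glutamate receptors (-0.02, 0.790), GABA receptors and transport (-0.00, 0.859) and potassium channels (0.01, 0.904). Among Rho effectors, the kinase Cit differed by -0.39 (SE 0.152, adjusted p = 0.601). The probes of 4 named genes disagreed in sign: Ppp1r12b (-0.12), Itsn1 (0.13), Shank1 (0.08) and Akap6 (0.08) lay on the other side of 0 when all their probes were averaged. Neuron and region lists also did not pass: dentate granule neurons (0.02, 0.790), CA1 (0.03, 0.708), CA3 and CA2 (0.00, 0.859), interneurons (-0.01, 0.859), adult neurogenesis (-0.04, 0.708), neocortex (-0.01, 0.859), striatum and septum (0.01, 0.909) and thalamus and habenula (-0.04, 0.0676). Nor did astrocytes (-0.02, 0.128), endothelium (0.01, 0.790), pericytes and fibroblasts (0.09, 0.904), erythrocytes (0.10, 0.357) and immune activation (0.09, 0.708). Neuropeptides (0.01, 0.853), cholesterol synthesis (-0.02, 0.128), the core clock (0.03, 0.272), clock outputs (0.02, 0.708), glucocorticoid response (0.03, 0.708), heat shock proteins (-0.00, 0.708), cold-inducible genes (0.05, 0.128), the unfolded protein response (-0.01, 0.708) and the X-linked neighbours of Ophn1 (0.03, 0.357) did not pass either. Without the 11 arrays high in Ttr, some of these lists had larger means. Among them were dentate granule neurons (0.14), pericytes and fibroblasts (0.25), glucocorticoid response (0.13) and cholesterol synthesis (-0.092). Most groups held 1 array in that fit. Thalamus and habenula passed with the choroid plexus covariate (-0.086, adjusted p = 0.00471) but lay at 0.17 without the arrays high in Ttr (adjusted p = 0.840).

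Compared at single times, KO and WT differed in Ophn1 at each time, by -2.05, -2.02, -1.89 and -1.79 at 0, 6, 12 and 18 h (adjusted p = 2.18e-06, 4.87e-07, 3.88e-06 and 3.14e-06). Fits with fewer arrays ended some of these calls at similar differences. With only the arrays of that time it was -1.89 at 12 h (adjusted p = 0.0542) and -1.79 at 18 h (0.253), and without the 11 arrays high in Ttr -2.11, -2.10 and -1.85 at 0, 6 and 12 h (0.164, 0.0679 and 0.0927). At 0 and 6 h Ophn1 was the only call. In limma 442 and 613 features had an unadjusted p under 0.05, fewer than the 1238.6 expected by chance. At 12 h Ugt2b5 was called as well. It was well above background on the 2 WT arrays and on none of the 3 KO arrays, at least 2.08-fold lower in KO (adjusted p = 3.72e-08). At 18 h 5 genes were higher in KO. With the same scaling, Dsg1c was at least 4.46-fold and Arhgap33os, an antisense transcript of a Rho GAP gene, at least 2.18-fold higher (limma adjusted p = 0.0137 each). Neither was well above background on any WT array of 18 h. Rnase10 was higher by 1.33 (SE 0.197, adjusted p = 0.0265) and Cpb2 by 1.32 (SE 0.199, adjusted p = 0.0265). The fifth was the vomeronasal receptor Vmn1r197. The 18 h values of Rnase10, Cpb2 and Vmn1r197 were chosen after they were seen. Of the 5 probes, 3 carry the heptamer CCTAACC and 1 TGTGCTG. Further probes with these heptamers also lay higher in KO at 18 h (medians 0.12 and 0.05). The 5 calls may therefore not be 5 separate gene changes.

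A bound set by background was computed as the mean level of the bright group against, on each array of the dim group, the higher of the probe's own level and the lowest level well above background. With normexp the log2 differences lay below the bounds, at 0.72 for Dsg1c and 0.38 for Arhgap33os at 18 h. For Ugt2b5 at 12 h the normexp value was -0.40. The bounds are therefore those of the fit reported here, not of every processing. At 18 h the choroid plexus marker Ttr was above 4 on 1 of 3 KO and 1 of 3 WT arrays. With slide as a block, 1, 1, 6 and 7 features passed at 0, 6, 12 and 18 h, and within a slide each genotype had at most 1 array per time. Of the 6 features called at 18 h, 4 were among those 7. Cpb2 and Vmn1r197 lost their calls with slide as a block (adjusted p = 0.0512 each), normexp (0.141 and 0.104), quantile normalization (0.0875 and 0.0636) and the authors' deposited table (0.0907 and 0.0614), as did Rnase10, Cpb2 and Vmn1r197 with no filter (0.0565 each) and without the arrays high in Ttr (0.863, 0.863 and 0.0981). Vmn1r197 also lost its call with the choroid plexus covariate (0.0534) and without KO 0 h replicate 1, KO 6 h replicate 2, KO 18 h replicate 1, WT 6 h replicate 1 or WT 18 h replicate 1 (0.0527 to 0.138), Rnase10 without KO 18 h replicate 1 (0.0531) and Cpb2 without WT 18 h replicate 1 (0.119). The calls of Dsg1c and Arhgap33os at 18 h were lost without KO 18 h replicate 2 (adjusted p = 0.0702 and 0.101), KO 18 h replicate 3 (0.122 each), WT 18 h replicate 2 (0.145 each) or WT 18 h replicate 3 (0.101 each), and without each of these 4 arrays 1 feature passed at 18 h. Without KO 6 h replicate 1, KO 12 h replicate 2 or KO 12 h replicate 3, 10, 10 and 16 passed. Normexp background correction ended the calls of Arhgap33os at 18 h (adjusted p = 0.129) and Ugt2b5 at 12 h (0.0935). That of Dsg1c was also lost with only the 18 h arrays (0.0548) and without the arrays high in Ttr (0.105), and that of Ugt2b5 with only the 12 h arrays (0.0944) and without those high in Ttr (0.0581). At 12 h, 291 features passed without WT 12 h replicate 2 and 64 without WT 12 h replicate 3. At 0 h, 11 passed without WT 0 h replicate 1, 8 without WT 0 h replicate 2 and 2 without KO 0 h replicate 1, and at 6 h 2 passed without KO 6 h replicate 3.

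**Figure D3:**
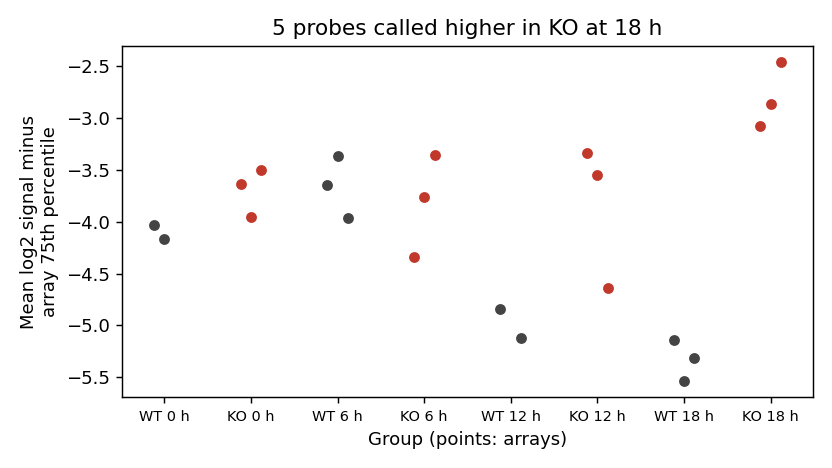
Mean level of the 5 probes called higher in KO at 18 h (vertical axis, log2 signal minus the array's 75th percentile) in the 8 groups of genotype and collection time (horizontal axis). Points are single arrays, grey for WT and red for KO. The 3 KO arrays of 18 h lie between -3.08 and -2.46, above the highest other array at -3.33, and the 3 WT arrays of 18 h between -5.54 and -5.14.

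Far more genes differed with collection time than with genotype. Collection time went together with slide row, as genotype did with slide column. Over both genotypes 2811 of 24772 features differed between the 4 times in limma, and 6488 had an unadjusted p under 0.05. The endoplasmic reticulum chaperone Hspa5 was 2.20-fold higher at 18 h than at 6 h (log2 1.14, SE 0.0701, adjusted p = 1.07e-06), and Sdf2l1 of the same compartment 2.80-fold (1.49, SE 0.0907, adjusted p = 1.07e-06). Nr1d1, a nuclear receptor that represses clock genes, was 2.06-fold higher at 6 h than at 18 h (1.04, SE 0.07, adjusted p = 1.9e-06). Plin4, a lipid droplet protein induced by glucocorticoids, was 6.89-fold higher at 12 h than at 6 h (2.78, SE 0.227, adjusted p = 1.52e-05). Among the passing features, 240, 767, 513 and 1291 were highest at 0, 6, 12 and 18 h and 233, 830, 840 and 908 lowest. The median fold between the highest and lowest time was 1.35, and 177 features reached at least 2-fold. The highest and lowest times were 12 h apart for 1567.

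Most of the 24 named genes with the smallest p were highest at 18 h and lowest at 6 h. Besides Hspa5 and Sdf2l1 these were the secreted stress factor Manf (1.002), Creld2 (0.92), the prolyl hydroxylase P4ha1 (0.97), the HSP90 partner Chordc1 (0.77), the splicing factors Sfpq (0.62) and Luc7l (0.70), Adam8 (1.32), Dok3 (1.004), Mkks (0.97), Zfp236 (0.59), Ccdc151 (0.66), Zbtb40 (1.05) and Saysd1 (0.95). Derl3 (1.31) and Pdia6 (0.90) were highest at 18 h and lowest at 12 h. Highest at 12 h were Plin4, Ugt2b5 (well above background only in WT at 12 h), the hypoxia-inducible factor subunit Hif3a (2.31), adenosine deaminase Ada (1.61) and the cold-inducible RNA-binding protein Cirbp (1.03). Nr1d1 and Accs (0.83) were highest at 6 h.

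With slide as a block 4791 features passed, 2785 of them among the 2811. Within slides 1, 2 and 3, 328, 0 and 5 passed and 6576, 2989 and 4353 had an unadjusted p under 0.05 in limma. Sdf2l1 differed by 1.496, 1.40 and 1.56 within the slides, Nr1d1 by 0.88, 1.08 and 1.17 and Plin4 by 3.03, 2.72 and 2.48. Choroid plexus genes lay higher at 6 h than at 18 h by 1.06 (17 of 17 members, camera adjusted p = 0.208) and higher at 0 h than at 12 h by 0.32 (15 of 17, adjusted p = 0.690), with 0 members passing or at an unadjusted p under 0.05 in limma. On slide 1, however, the list's mean was lower at 6 h (-2.76 in KO, -2.75 in WT) than at 18 h (-0.075 and 1.40). For 0 h minus 12 h it was 0.58, -0.30 and -0.15 within slides 1 to 3. With the choroid plexus signal as a covariate 2933 features passed. With only the 11 arrays low in Ttr, 4 features passed.

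Core clock genes varied with time in 11 of 24 measured members, and 15 passed adjusted over the list alone. Nr1d1 was highest at 6 h. Dbp, a transcription factor driven directly by the clock, was highest at 12 h and lowest at 0 h (1.21, SE 0.121, adjusted p = 8.27e-05), as were the repressor Ciart (1.72, SE 0.168, adjusted p = 4.41e-05), Per3 (0.56, adjusted p = 9.23e-04) and Nr1d2 (0.69, adjusted p = 3.72e-04). Arntl, an activator in the clock loop, was highest at 0 h and lowest at 12 h (0.59, SE 0.0957, adjusted p = 0.00452). Per2 was highest at 18 h (0.72, SE 0.0916, adjusted p = 1.54e-04), as was the repressor Nfil3 (0.61, adjusted p = 3.68e-04), and Cry1 at 12 h (1.22, SE 0.238, adjusted p = 0.0121). Per1 (12 h against 0 h, 0.57, adjusted p = 0.0324) and Rora (12 h against 18 h, 0.79, adjusted p = 0.0412) passed as well, but in 6 and 13 of the 22 fits that left out 1 array they did not, with adjusted p up to 0.113 without WT 12 h replicate 3 and 0.159 without WT 12 h replicate 2.

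The other 13 members did not pass. Their spans between the highest and lowest time were 0.24 for Clock (adjusted p = 0.052), 0.33 for Tef (adjusted p = 0.0507), 0.37 for Hlf, 0.45 for Bhlhe41, 0.34 for Npas2, 0.33 for Rorc, 0.25 for Fbxl21, 0.18 for Rorb and Bhlhe40, 0.17 for Csnk1d, 0.15 for Csnk1e, 0.13 for Cry2 and 0.11 for Fbxl3. The core clock list lay lower at 0 h than at 12 h by a mean of -0.32 (camera adjusted p = 1.97e-07, adjusted p = 0.129 with an estimated correlation), with -0.34, -0.26 and -0.32 within slides 1 to 3 and -0.31 with slide as a block.

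**Figure D4:**
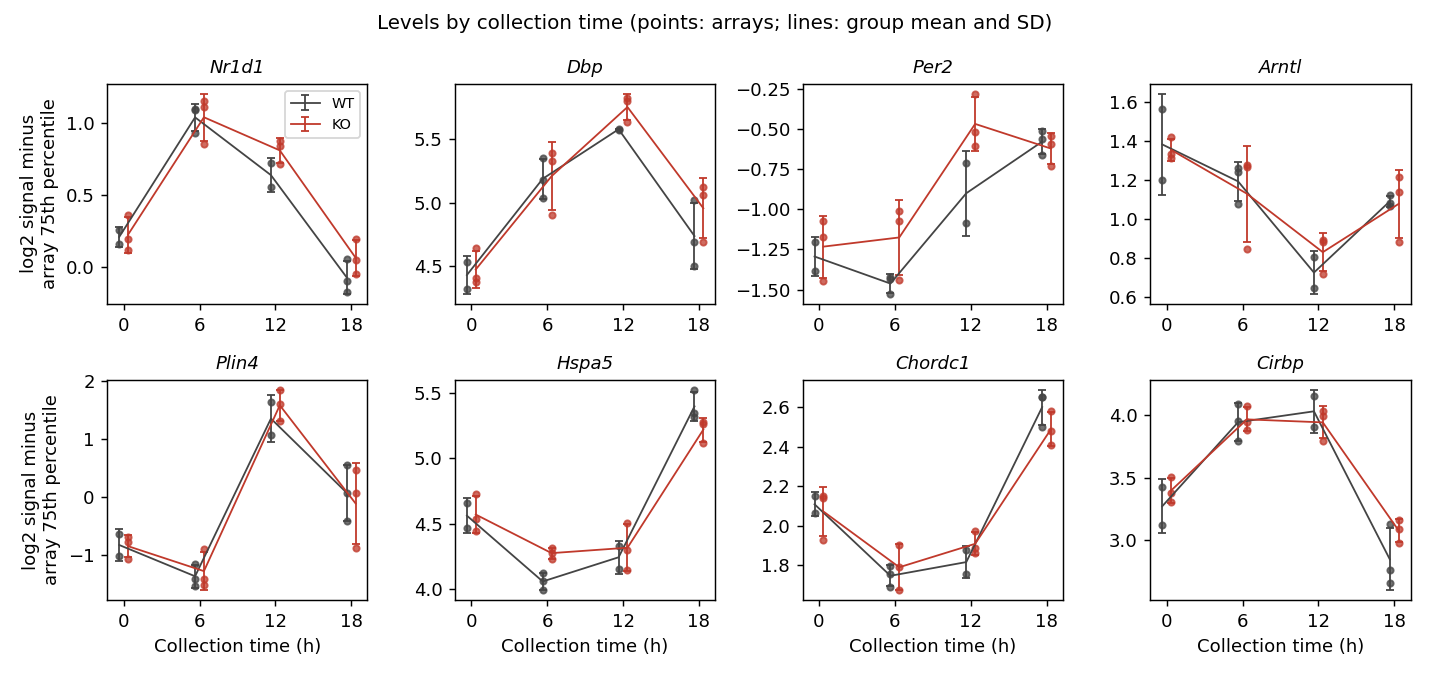
Levels of 8 genes (vertical axes, log2 signal minus the array's 75th percentile) against collection time in h (horizontal axes). Points are single arrays; lines join group means, with bars for the SD, grey for WT and red for KO. The upper row shows clock genes, with Dbp highest at 12 h and Arntl lowest there; the lower row shows Plin4 peaking at 12 h, Hspa5 and Chordc1 at 18 h, and Cirbp lowest at 18 h, in both genotypes.

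Clock output genes passed in 10 of 12 members, and 10 adjusted over the list alone. The deubiquitinase Usp2 was highest at 6 h (0.42, adjusted p = 0.00168), Cys1 at 18 h (1.12, adjusted p = 3.67e-05) and Tspan4 at 12 h (0.71, adjusted p = 2.91e-04). The list was lower at 0 h than at 12 h by -0.41 (camera adjusted p = 2.51e-06, adjusted p = 0.00626 with an estimated correlation; -0.43, -0.40 and -0.38 within slides). Glucocorticoid response genes passed in 13 of 18 members, 11 of them highest at 12 h, and 15 adjusted over the list alone. Tsc22d3, which encodes the leucine zipper protein GILZ, was highest at 12 h (1.16, SE 0.107, adjusted p = 2.6e-05), as were Map3k6 (1.05) and Sult1a1 (1.05). The list was lower at 0 h than at 12 h by -0.74 (adjusted p = 8.24e-21, adjusted p = 0.00911 with an estimated correlation; -0.84, -0.62 and -0.65 within slides) and lower at 6 h than at 18 h by -0.22 (adjusted p = 0.0223, adjusted p = 0.850 with an estimated correlation; 0.067 without WT 18 h replicate 2).

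Stress chaperones were highest at 18 h. Unfolded protein response genes passed in 14 of 18 members, all 14 highest at 18 h, and 16 adjusted over the list alone; Hsp90b1, the endoplasmic reticulum member of the HSP90 family, spanned 0.48 (adjusted p = 6.39e-05). The list was lower at 6 h than at 18 h by -0.54 (adjusted p = 2.11e-18, adjusted p = 0.00911 with an estimated correlation; -0.63, -0.47 and -0.53 within slides). Heat shock proteins passed in 11 of 16 members, all 11 highest at 18 h, and 12 adjusted over the list alone, among them the co-chaperones Stip1 (0.38, adjusted p = 4.91e-04), Fkbp4 (0.53, adjusted p = 4.11e-04) and Dnaja1 (0.46, adjusted p = 8e-04). All 16 were lower at 6 h than at 18 h, by -0.39 on average (adjusted p = 1.36e-12, adjusted p = 0.0389 with an estimated correlation and 0.0602 with an estimated correlation and slide as a block; -0.34, -0.34 and -0.48 within slides). Cold-inducible RNA-binding genes moved the other way. They passed in 4 of 5 members, and 5 adjusted over the list alone: Rbm3 was highest at 12 h (0.65, adjusted p = 3.43e-04), and so was Rbmx (0.40, adjusted p = 4.01e-04). All 5 were higher at 6 h than at 18 h, by 0.43 (adjusted p = 4.84e-06, adjusted p = 0.0389 with an estimated correlation; 0.42, 0.38 and 0.48 within slides), and the list was lower at 0 h than at 12 h by -0.30 (adjusted p = 5.25e-04, adjusted p = 0.129 with an estimated correlation).

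Between 0 and 12 h, 8 further list calls were made, none of which held with an estimated correlation (adjusted p of 0.390 to 0.953). Dentate granule neuron genes were higher at 0 h by 0.38 (16 of 17 members, adjusted p = 5.19e-07), neurogenesis genes by 0.28 (adjusted p = 0.0358), ependyma genes by 0.47 (13 of 13, adjusted p = 4e-04; choroid plexus 0.32), unfolded protein response genes by 0.09 (adjusted p = 0.0378), heat shock genes by 0.07 (adjusted p = 0.0378) and scaffold genes by 0.08 (adjusted p = 0.0358). Thalamus and habenula genes were lower by -0.21 (adjusted p = 0.0263) and oxidative phosphorylation genes by -0.05 (42 of 50, adjusted p = 0.0281). Of these, the dentate list alone passed in all 22 fits that left out 1 array. The ependyma call was lost without WT 0 h replicate 1 or WT 12 h replicate 3 (adjusted p = 0.331 and 0.233). The thalamus call was lost without KO 0 h replicate 1, KO 12 h replicate 2 or WT 12 h replicate 2 (0.0578 to 0.819), and the neurogenesis call without KO 0 h replicate 2, KO 12 h replicate 1, WT 0 h replicate 1 or WT 12 h replicate 3 (0.0683 to 0.118). The scaffold call was lost without KO 0 h replicate 3, KO 12 h replicate 1, WT 0 h replicate 2 or WT 12 h replicate 2 (0.101 to 0.599), and the heat shock call without KO 0 h replicates 2 or 3, KO 12 h replicate 1, WT 0 h replicate 2 or WT 12 h replicate 2 (0.0643 to 0.311). For oxidative phosphorylation the arrays were KO 0 h replicate 3, KO 12 h replicates 1 or 2, WT 0 h replicate 1 and WT 12 h replicate 3 (0.0503 to 0.217). For the unfolded protein response they were KO 0 h replicate 2, KO 6 h replicate 3, KO 12 h replicates 1 or 3, WT 0 h replicate 1, WT 12 h replicate 2 and WT 18 h replicate 1 (0.0503 to 0.230). With slide as a block the adjusted p was 0.0706 for the unfolded protein response and 0.0843 each for the scaffold and neurogenesis. Without the 11 arrays high in Ttr it was 0.502 for the unfolded protein response, 0.352 for the scaffold, 0.0974 for neurogenesis and 0.539 for thalamus and habenula, which then lay higher at 0 h by 0.18. The means of heat shock and oxidative phosphorylation genes were then 0.11 and -0.11. Others between 0 and 12 h were -0.24 for immediate early genes, 0.22 for myelin, 0.19 for oligodendrocyte precursors, -0.52 for erythrocytes and -0.13 for ribosomal proteins. Between 6 and 18 h they were -0.13 for myelin, -0.34 for ependyma, -0.065 for oxidative phosphorylation and -0.077 for ribosomal proteins. In that fit each genotype had 1 array at 0 h and 1 at 12 h. Cholesterol synthesis genes were lower at 0 h than at 12 h by -0.15 (adjusted p = 9.92e-05, adjusted p = 0.637 with an estimated correlation) and higher at 6 h than at 18 h by 0.24 (19 of 20 members, adjusted p = 4.84e-06, adjusted p = 0.417 with an estimated correlation), for example the sterol sensor Insig1 (0.44, adjusted p = 0.00391). Between 6 and 18 h, immediate early genes were lower at 6 h in 22 of 24 members, by -0.36 (adjusted p = 6.06e-05, adjusted p = 0.850 with an estimated correlation), with Arc (1.14, SE 0.206, adjusted p = 0.00851) and Dusp6 (0.71, adjusted p = 0.00101) highest at 18 h. Dentate granule genes were lower at 6 h by -0.33 (adjusted p = 0.0014, adjusted p = 0.850 with an estimated correlation), and by 0.03, -0.29 and -0.75 within slides 1 to 3. Pericyte and fibroblast genes were higher at 6 h by 0.39 (adjusted p = 0.0326, adjusted p = 0.850 with an estimated correlation), and choroid plexus genes lay higher by 1.06. The pericyte call was lost with slide as a block (adjusted p = 0.0706), without the arrays high in Ttr (0.17, adjusted p = 0.143) and without KO 6 h replicates 2 or 3, KO 18 h replicate 1 or WT 18 h replicate 3 (0.0501 to 0.0998).

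Single members of other lists varied with time. Rho GAPs and GEFs passed in 8 of 32 members (10 adjusted over the list alone), with Trio highest at 18 h (0.50, adjusted p = 0.00186) and Srgap2 at 6 h (0.51, adjusted p = 0.00237). Among Rho effectors 1 of 29 passed (1 adjusted over the list alone), the cofilin phosphatase Ssh1, highest at 18 h (0.44, adjusted p = 1.78e-04). In cAMP signalling 2 of 29 passed (4 adjusted over the list alone), Crem (18 h, 0.37) and Adcy8 (6 h, 0.62). In the endothelium 3 of 15 passed (3 adjusted over the list alone): the tight junction gene Cldn5 was highest at 0 h (0.87, adjusted p = 1.82e-04), and the glucose transporter Slc2a1 (0.63, adjusted p = 3.68e-04) and Ly6c1 (0.47) at 12 h. Adult neurogenesis passed in 4 of 14 (4 adjusted over the list alone), including Sox11, a factor of immature neurons (18 h, 0.74, adjusted p = 1.24e-04). Astrocytes passed in 4 of 16 (5 adjusted over the list alone; Sox9 at 0 h, 0.50), microglia in 4 of 17 (4; Cx3cr1 at 6 h, 0.49), oligodendrocyte precursors in 2 of 8 (2; Gpr17 at 18 h, 0.48), myelin in 2 of 19 (2; Opalin at 0 h, 0.70), immediate early genes in 6 of 24 (6) and cholesterol synthesis in 3 of 20 (7).

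Among neuronal lists, glutamate receptors passed in 2 of 25 (2 adjusted over the list alone; Grin2b at 18 h, 0.45), neuropeptides in 1 of 28 (4; the oxytocin receptor Oxtr at 18 h, 0.71, adjusted p = 0.00318), potassium channels in 3 of 25 (3; Kcnip4 at 12 h, 0.37), GABA receptors in 2 of 20 (2), dentate granule neurons in 2 of 17 (2; Trpc6 at 18 h, 0.73), CA1 in 1 of 13 (2; Zdhhc23 at 18 h, 0.34), CA3 and CA2 in 1 of 15 (4), interneurons in 1 of 18 (5), clathrin endocytosis in 2 of 24 (1; Picalm at 18 h, 0.27) and the postsynaptic scaffold in 1 of 22 (0 adjusted over the list alone, 8 at an unadjusted p under 0.05). Neighbouring regions passed in 2 of 14 for thalamus and habenula (2; Ramp3 at 12 h, 1.296), 2 of 15 for neocortex (4; Krt12 at 6 h, 1.35) and 1 of 14 for striatum and septum (0, and 3 at an unadjusted p under 0.05). Pericytes passed in 1 of 15 (1; Pdgfrb at 0 h, 0.32) and the neighbours of Ophn1 in 3 of 30 (3). In limma 0 members passed among synaptic vesicle release, immune activation, ependyma, erythrocyte, oxidative phosphorylation, ribosomal protein and choroid plexus genes, where 9, 3, 3, 0, 0, 0 and 0 had an unadjusted p under 0.05.

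Taken alone, WT arrays gave 711 features that differed with time and KO arrays 391, and 255 passed in both. Of the 711 called in WT, 687 (96.6%) went the same way in KO between their highest and lowest WT times, with a median log2 difference of 0.63 in WT and 0.41 in KO, and 581 had the same highest time. Of the 391 called in KO, 383 (98.0%) went the same way in WT, with medians of 0.64 in KO and 0.52 in WT, and 326 had the same highest time. Each median is larger in the genotype in which the genes were chosen, and no test of the difference in these medians was made. Dbp spanned 5.75 ± 0.11 at 12 h to 4.47 ± 0.14 at 0 h in KO (SD, n = 3 each) and 5.58 ± 0.00 to 4.43 ± 0.15 in WT (SD, n = 2 each). With slide as a block, 1467 passed in WT and 1114 in KO. The WT count was 440, 284 and 380 without WT 6 h replicates 1, 2 and 3, 323 without WT 18 h replicate 1 and 181 without WT 18 h replicate 3. The KO count was 235 without KO 0 h replicate 2, 216 and 259 without KO 6 h replicates 2 and 3, 221 and 180 without KO 12 h replicates 1 and 3, and 234, 141 and 158 without KO 18 h replicates 1, 2 and 3. No slide held more than 1 array of a genotype per time, so neither can be fitted within a slide.

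Whether the time course itself differed between genotypes was tested as an interaction. In limma 468 features had an unadjusted p under 0.05, fewer than the 1238.6 expected by chance, a shortfall whose cause was not tested. Ugt2b5 was the only feature that passed (limma adjusted p = 3.78e-06). Its level was -4.49 ± 0.44 (SD, n = 2) in WT at 12 h and not well above background on any array of the other 7 groups. The call was lost with normexp background correction (adjusted p = 1), with a trended, robust variance (adjusted p = 0.737), with the cosine and sine (adjusted p = 1) and without the 11 arrays high in Ttr (adjusted p = 0.0787). No core clock member had an unadjusted interaction p under 0.05 in limma, the lowest being 0.101 for Per2, which lay at -0.47 ± 0.17 in KO (SD, n = 3) and -0.90 ± 0.26 in WT (SD, n = 2) at 12 h. In limma, 0 members of each of the 39 lists passed, over all genes or adjusted over the list alone. Of their members, 1 at most had an unadjusted p under 0.05 in any list, apart from 2 in microglia and 2 in oligodendrocyte precursors. With 1 array left out, 16 features passed (WT 12 h replicate 2), 14 (WT 12 h replicate 3), 6 (WT 0 h replicate 1), 4 (WT 0 h replicate 2) or 2 (KO 6 h replicate 3).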

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

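All tests of the choroid plexus signal and of the 18 h probes reported here were chosen only after the result was seen, as were the fits with the choroid plexus covariate and without the 11 arrays high in Ttr. So were the counts over other splits with slide as a block. The other counts over splits of the arrays were planned.

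Negative control spots had a mean net signal of 101 on WT 0 h replicate 1 and of 25.6 to 29.9 on the other 4 arrays of 0 h, a gap beyond Dixon's critical value. It was the only one so marked among 21 sets of arrays tested, and chance marks about 1 in 20. The gap over range was 0.943 against a critical value of 0.71. In every pair of a KO and a WT array of one slide and time, the WT array had the higher mean. At 6 h, slides 1 to 3 gave 39.9, 32.5 and 29.1 in WT and 27.3, 29.5 and 26.5 in KO. This difference was seen afterwards. It goes with slide column as well as genotype, and its bearing on the calls of dim probes between KO and WT was not tested.

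The time course of Ugt2b5 differed between KO and WT (interaction adjusted p = 3.78e-06), as its signal was well above background only on the 2 WT arrays of 12 h, at a mean of -4.49.

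Choroid plexus genes differed by a wide margin between arrays of one group, with Ttr between 6.18 and 8.20 on 11 arrays and between -2.03 and 1.997 on the others. Slide accounted for 11.4% of the variance of the list's mean and genotype for 5.59%, and 82.2% lay within the 8 groups, whose arrays share genotype and time, which argues against a slide batch and against genotype as the whole cause. Choroid plexus tissue taken along with some hippocampi may account for it: the median r of the other 16 members with Ttr was 0.968 over the 22 arrays, which form separate clusters, 0.974 among the 11 high arrays (lowest 0.923) and 0.526 among the other 11 (lowest 0.0278), and 11 of the 17 members were well above background on every low array. No other biological explanation was tested.

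Of the 5 probes called higher in KO at 18 h, those of Dsg1c, Arhgap33os, Rnase10, Cpb2 and Vmn1r197, 3 carry the heptamer CCTAACC and 1 TGTGCTG. Leaving out these and 2 and 5 more among the 14 probes in which the heptamers were noticed, 80 further probes with CCTAACC had a median difference of 0.12 at 18 h and 327 with TGTGCTG one of 0.05, above all of 10000 random probe sets of their size (percentile 100 for each), and 13 and 8 of them exceeded 1 against 0.341% of kept probes. The reverse complements showed medians of 0.01 and -0.00 and 0 probes above 1. Binding of some labelled product to the shared heptamers may therefore contribute. A genotype effect at 18 h stays open and untested. In the mean of the 5 probes, 0 arrays of the other 7 groups lay above the lowest KO 18 h array (-3.08, highest other -3.33). Probes called for being higher there decide nothing, however. Nor was the difference in that mean confined to 18 h. At 12 h the KO arrays (-4.64 to -3.33) lay above both WT arrays (-5.12 and -4.84). At 0 h they did so too (-3.95 to -3.50 against -4.16 and -4.03). At 6 h the genotypes overlapped (-4.34 to -3.35 in KO, -3.96 to -3.36 in WT).

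For the count of 6 genes between KO and WT over the 4 times, chance could not be excluded. Of 100 splits, 7 gave as many, the highest other count being 1922. The splits test the count and not single genes. Ophn1, 1 of the 6, lay lower on every KO array (-1.06 to -0.32) than on every WT array (0.82 to 1.20). Splits with 1922, 732 and 172 genes point to a structure of the arrays. The first 2 called 7 and 8 of the 8 slide 1 arrays KO, but a split with the same make-up by slide as the first gave 10 genes, so slide alone does not account for such a count. In the split with 1922 genes, 8 of the 11 arrays high in Ttr were called KO, and in the one with 732, 6. The real count was 155 with slide as a block. When genotypes were exchanged within the 10 pairs of one slide and time, so that slides stayed balanced, 1 of 100 splits, the real one, reached it, the highest other was 1, and chance could be excluded. The exchange also swaps slide column, so it cannot tell genotype from column. Of the 155 features, 22 are linked by shared sequence and are not independent. Redrawing collection times likewise redraws slide row, so those splits cannot tell time from row. For the 2811 genes that differed with time over both genotypes, 1 of 100 splits was as large (highest other 14). For the 391 in KO it was also 1 of 100 (highest other 25), so chance could be excluded for both. It could not be excluded for the interaction (1 gene, 30 of 100 splits as large, highest other 279), for the 10 lists between KO and WT (46 of 100, highest other 18) or for the 21 list calls over time (42 of 100, highest other 35, not redone with slide as a block). Nor could it with slide as a block for the interaction (1 gene, 34 of 100, highest other 24) and the lists between KO and WT (9 lists, 56 of 100, highest other 20). At 6 h (1 gene, Ophn1, 4 of 10 splits, highest other 4) and 18 h (6 genes, 1 of 10 splits, highest other 0) the splits are too few to judge the counts.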

How the results depend on the processing

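The fits with the choroid plexus covariate, alone or with slide as a block, and without the 11 arrays high in Ttr were chosen only after the data were seen. The limits include the 2 or 3 arrays per group, the 3 slides and, for dim probes, signal over background. At single times only bounds are given for Ugt2b5, Dsg1c and Arhgap33os where a group was not well above background. With normexp their differences fell below these bounds. Ophn1 stayed lower in KO in every fit, from -1.99 to -1.90 when 1 array was left out, -1.71 with normexp and -1.49 with the mean of its probes. Counts within 1.5 times of those reported were found for all comparisons with quantile normalization (8 genes between KO and WT and 3018 with time) and the authors' deposited table (7 and 3006), and with the mean of a gene's probes. Normexp left 0 genes in the interaction (488 at an unadjusted p under 0.05 in limma), as did the strict filter (377), the trended, robust variance (404) and the cosine and sine (457), and every probe on its own gave 2. No filter gave 2 genes at 0 h, 3 at 18 h, 330 with time in WT and 162 in KO; the strict filter gave 1 at 12 h and 3 at 18 h. The cause was not tested, except that the filters change the number of genes tested by construction.

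Slide as a block gave 155 genes between KO and WT, 6 at 12 h, 4791 with time, 1467 with time in WT and 1114 in KO; with the choroid plexus covariate added the counts were 133, 9, 5163, 1882 and 1110, with 15 at 18 h. The cause was not tested. With the replicate number as a block they were 143 between KO and WT, 425 at 12 h, 1 at 18 h, 4946 with time, 2238 in WT, 914 in KO and 12 in the interaction, with 7 lists between KO and WT and 17 over time. That block ended the 18 h calls of Dsg1c and Arhgap33os (limma adjusted p = 0.0577 each) and of Rnase10, Cpb2 and Vmn1r197 (0.0616 each). Between KO and WT it ended the camera calls of oligodendrocyte precursors (adjusted p = 0.0528), the scaffold (0.0636) and choroid plexus (0.0715). Between 0 and 12 h it ended those of oxidative phosphorylation (0.127), thalamus and habenula (0.0507) and neurogenesis (0.0504). Arrays of one replicate number had a mean correlation of deviations of 0.194, against -0.097 for other pairs. Of 22 arrays, 17 correlated best with their own number. Only 48 of 70 pairs were over 0.1 and the lowest lay at -0.51, so the numbers are not taken as a pairing. For slide the values were close: 0.219 against -0.109, 49 of 70 pairs and 18 of 22 arrays. Arrays thus shared variation under both labels. These differ only for WT 12 h replicate 2, so the data hardly tell them apart.

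With only the 11 arrays low in Ttr, fewer by construction, 10 genes differed between KO and WT, 2 at 0 h, 4 at 6 h, 0 at 12 h (2299 at an unadjusted p under 0.05 in limma), 4 with time, 13 in WT, 5 in KO and 4 in the interaction. Only the 6 and 18 h arrays gave 1 gene between KO and WT, and only the arrays of that time 1 at 12 h and 2 at 18 h, with fewer arrays by construction. An estimated correlation left 0 lists between KO and WT (2 at an unadjusted p under 0.05 in camera) and 5 over time, since it allows for measured correlation within lists by construction.

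With each array left out in turn, the counts ranged from 5 to 46 between KO and WT, 1 to 11 at 0 h, 1 to 2 at 6 h, 2 to 291 at 12 h, 1 to 16 at 18 h, 1935 to 3187 with time, 181 to 901 in WT, 141 to 447 in KO, 1 to 16 in the interaction, 8 to 12 for lists between KO and WT and 16 to 23 for lists over time. The highest values at 12 h, over the 4 times and in the interaction came without WT 12 h replicate 2, and the lowest with time in WT and KO without WT 18 h replicate 3 and KO 18 h replicate 2. Each left-out array that moved a count by over 1.5 times is named beside it in the account of that comparison. The cause was not tested.

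Of 236 results on named genes 113 were called, and 87 of these kept their call with any array left out. Over the other settings the called ones kept their call 1381 times and lost it 190 times, 111 of these with only the arrays low in Ttr, and those not called passed 146 times. None of the called ones turned direction, but 19 values of genes not called did. With only the arrays low in Ttr, KO minus WT became -0.040 for Cirbp, 0.037 for Grm1, 0.026 for Lhx6, -0.043 for Tac2, -0.035 for Oxtr, 0.093 for Npnt and -0.030 for Stat1, and the time difference -0.018 for Csnk1e and -0.19 for Msx1. With only the 6 and 18 h arrays Relt became 0.0040 and Scnn1a -5.52e-04, and with each array left out in turn the time difference of Rorb ranged from -0.020 without WT 12 h replicate 2 to 0.38 without WT 12 h replicate 3. The cause was not tested. With every probe on its own Ppp1r12b became 0.29, Itsn1 -0.11 and Shank1 -0.22, and with the mean of a gene's probes Ppp1r12b 0.084, Itsn1 -0.045, Shank1 -0.075 and Akap6 -0.0051, as probes of these genes differ in sign.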

Other observations

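The test of shared sequence and the counts on the X chromosome were chosen only after the result was seen. The tests of the 3' end, of the neighbours of Ophn1 and of the heat shock and cold-inducible genes were set down before their results were seen.

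Among the 155 features called between KO and WT with slide as a block, 22 probes, all lower in KO (-0.45 to -0.28), were linked by shared stretches of 15 bases, against at most 4 in any random set of as many probes. They may therefore read one transcript family, and Hmg1l1 is among them. With slide as a block an Hmgb1 probe that shares 15 bases with the set was lower too (-0.32, limma adjusted p = 0.00205). So was 1 Hmgb1 probe that does not share them (-0.37, 0.00162). The other Hmgb1 probes lay between 0.0013 and 0.076 (adjusted p = 0.411 to 0.991), so the probes of that gene disagree. Labelled products that reach less far from the 3' end in KO could contribute too. In 2076 genes with a pair of probes, the upstream probe relative to the downstream one was lower in KO by a median of -0.0279 (exact permutation p = 0.00215), and over the 22 arrays this went with the set's mean at r = 0.459 (permutation p = 0.0318) and rho = 0.413 (permutation p = 0.057), with r = 0.587 without the 2 farthest arrays and 0.541, 0.592 and 0.891 within slides 1 to 3. These r values took the arrays of both genotypes together. The set was called for being lower in KO, and the upstream measure was lower there too. A positive r is therefore expected in part and decides nothing. A biological difference between the genotypes stays open, untested.

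Alleles carried along with the mutated Ophn1 could alter genes near it on the X chromosome. The 30 measured neighbours had a mean absolute t at percentile 98.4 of 10000 random lists matched on level, but at 84.8 with slide as a block. In limma 0 of them passed and 4 had an unadjusted p under 0.05, with differences from -0.28 to 0.31. Among the 155 features called with slide as a block, 13 lay on the X chromosome, Ophn1 included, or 8.39% against 3.81% of tested features. Of the other 12, 3 lay within 10 Mb of Ophn1, as did 17.1% of tested features on the X chromosome, and 2 belonged to the set linked by shared sequence. The explanation therefore stays open.

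Heat shock and cold-inducible genes moved oppositely over the day, and a state of the single animal, such as its body temperature, could set both. Their deviations from group and slide means correlated at r = -0.730 (permutation p = 1.1e-04, rho = -0.703, permutation p = 3.9e-04, r = -0.612 without the 2 farthest arrays). The permutations exchanged all 22 deviations as if independent. Removing the means left fewer free values, so these p-values may be too small. With group means alone removed, r was -0.0977 (permutation p = 0.667, rho = -0.048, permutation p = 0.833), and within slides 1 to 3 it was -0.753, -0.910 and -0.383. As the 2 values differ with the removal of slide, and body temperature was not among the measurements used here, the test cannot tell.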
